A study of Mus musculus with 12 samples.

How the data were processed

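Lung tissue of male BALB/c mice was profiled by RNA sequencing of polyadenylated RNA, with 1 library per mouse. Per the labels' protocols, 24 mice were divided at random into 4 groups of 6, and 3 mice per group were sequenced after 14 days of modelling. The groups were an untreated control, lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria) as 50 µL at 1 µg/µL, bovine lactoferrin (bLF, an iron-binding milk protein) at 200 mg/kg per day, and LPS with bLF (LPS+bLF). The labels state neither the route of LPS nor the day on which it was given.

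Per the labels, the tools HISAT2 2.1.0 and RSEM 1.2.8 and the genome build mm10 were used, with no role or order stated. Read length, strandedness, gene annotation and filters were not stated. Per the file headers, each deposited file gives a count and an FPKM (fragments scaled to gene length and library size) for each gene. The deposited counts were taken to be RSEM-style expected counts, since 4.1 to 5.9% of genes had a count that was not whole. All 12 deposited files list the same 17920 genes by ID, of which 17869 were matched by ID to the RefSeq table of GRCm38 (mm10), from which coordinates were taken.

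Expected counts were rounded, and genes with at least 0.5 FPKM in at least 3 of the 12 libraries were tested, which left 13735 genes. Libraries were scaled with TMM factors, and all 12 libraries entered 1 edgeR quasi-likelihood fit of 4 group means with 8 residual degrees of freedom. The comparisons were LPS versus control, LPS+bLF versus LPS, bLF versus control, LPS+bLF versus control, and the interaction, which is the bLF effect with LPS minus the bLF effect without it. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no minimum on the fold. The SE of a log2 fold change was derived from the quasi-likelihood F statistic of the fit with 3 libraries per group, and FPKM levels are given as mean ± SD. The comparisons, the filter, the thresholds, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The test written then was limma on log2(FPKM + 1), because the files were known only as FPKM. edgeR took its place once the files proved to hold counts, and the limma fit was kept as an alternative.

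Of 57 gene lists of pathways and cell type markers, 55 had at least 5 tested members and 2 had none. The lists held 1345 genes, of which 1264 were in the files and 1142 were tested. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 55 lists. At this preset its p rests on the spread over genes. It allows little for members that vary together between animals. The camera test was repeated with an estimated correlation for each list, with all 12 libraries and without LPS replicate 1. This omission with an estimated correlation was not listed among the alternatives fixed in advance, and no other omission was run with it. The fry test was run beside camera. It asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Members were also counted after adjustment over the list alone.

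Named genes followed a fixed rule. For each comparison with fewer than 6 called genes, the 6 genes with the smallest unadjusted p in each direction at a mean of at least 1 FPKM were named and given as values. For each called list, up to 4 called members were named, or the 2 members with the smallest p where none was called. A fixed set of inflammatory, epithelial, matrix and iron-related genes was to be given whatever its test. Part of this set is given here, and not always for each comparison. Genes named outside this rule are marked as chosen after their values were seen, and 1 gene that the rule names is not reported here.

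The code was tested on simulated counts for LPS versus control, drawn for the 13735 genes from the means, library sizes and dispersions of the 12 libraries, with 200 changed genes. At a true log2 fold change of 1, edgeR recovered 15% of the changed genes, limma 12% and DESeq2 36%. At 2, they recovered 76%, 73% and 86%. False calls numbered 3 for edgeR, 3 for limma and 38 for DESeq2. A simulated list of 19 members raised by 1 was called by camera (adjusted p = 2.56e-11) with 0 other lists called. Simulated genes were drawn independently, so this does not test camera on lists whose members vary together.

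The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, rescaling to TPM, upper-quartile scaling, quantile normalization, a fit of only the groups compared, array weights, a robust fit, a replicate block, leaving out each library in turn, a minimum absolute log2 fold change of 1, and the estimated correlation. The pseudocounts, TPM, quantile and array weight alternatives were run on the limma fit. Another 6 alternatives were added after seeing the data: the limma fit on log2(FPKM + 1) that had been written as the test, and, chosen only then, DESeq2, RLE factors, library size alone, the omission of LPS replicate 1 with LPS+bLF replicate 3, and the omission of 5 libraries that stood apart. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.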

Results

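Lung RNA was sequenced from 12 mice in 4 groups of 3: control, LPS, bLF and LPS+bLF. Total counts per library ranged from 16714327 to 17820645. A count of 0 allowed a level of up to 0.168 to 0.179 CPM (3 counts of the total), a limit that covers counting error only. The common biological coefficient of variation was 0.352, and it was 0.292 without LPS replicate 1.

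Libraries of the same group differed in the levels of marker genes of tissues and cell types. In the heatmap of gene list means, LPS replicate 1 was far above the control mean for neutrophil markers (2.09 on the log2 scale), glucocorticoid targets (1.96) and cell cycle genes (1.56), and far below it for NK cell and cytotoxic lymphocyte markers (−2.34), B cell markers (−1.95) and T cell markers (−0.95). Saa3, an acute-phase protein of inflamed tissue, reached 3021.2 FPKM in this library, against 36.25 and 30.39 in the other LPS libraries. The median correlation of LPS replicate 1 with the other libraries was 0.884, where the other 11 had 0.918 to 0.973, and it had 3067 genes at 0 where the others had 1499 to 1963. Ucp1, the uncoupling protein of brown fat, was at 88.08 FPKM in control replicate 1, 57.37 in bLF replicate 1 and 157.72 in LPS+bLF replicate 2, and these libraries also led in cardiac muscle genes (1.6, 3.36 and 3.33). LPS+bLF replicate 3 had the highest means for skeletal muscle genes (5.48) and for basal cell and squamous epithelium markers (5.32), with the muscle creatine kinase Ckm at 807.15 FPKM and the keratin Krt5 at 98.34 FPKM. Scgb1a1, the secretoglobin of club cells, took 23.8% of the counts of control replicate 2 and 1.7 to 7.4% elsewhere.

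**Figure D1:**
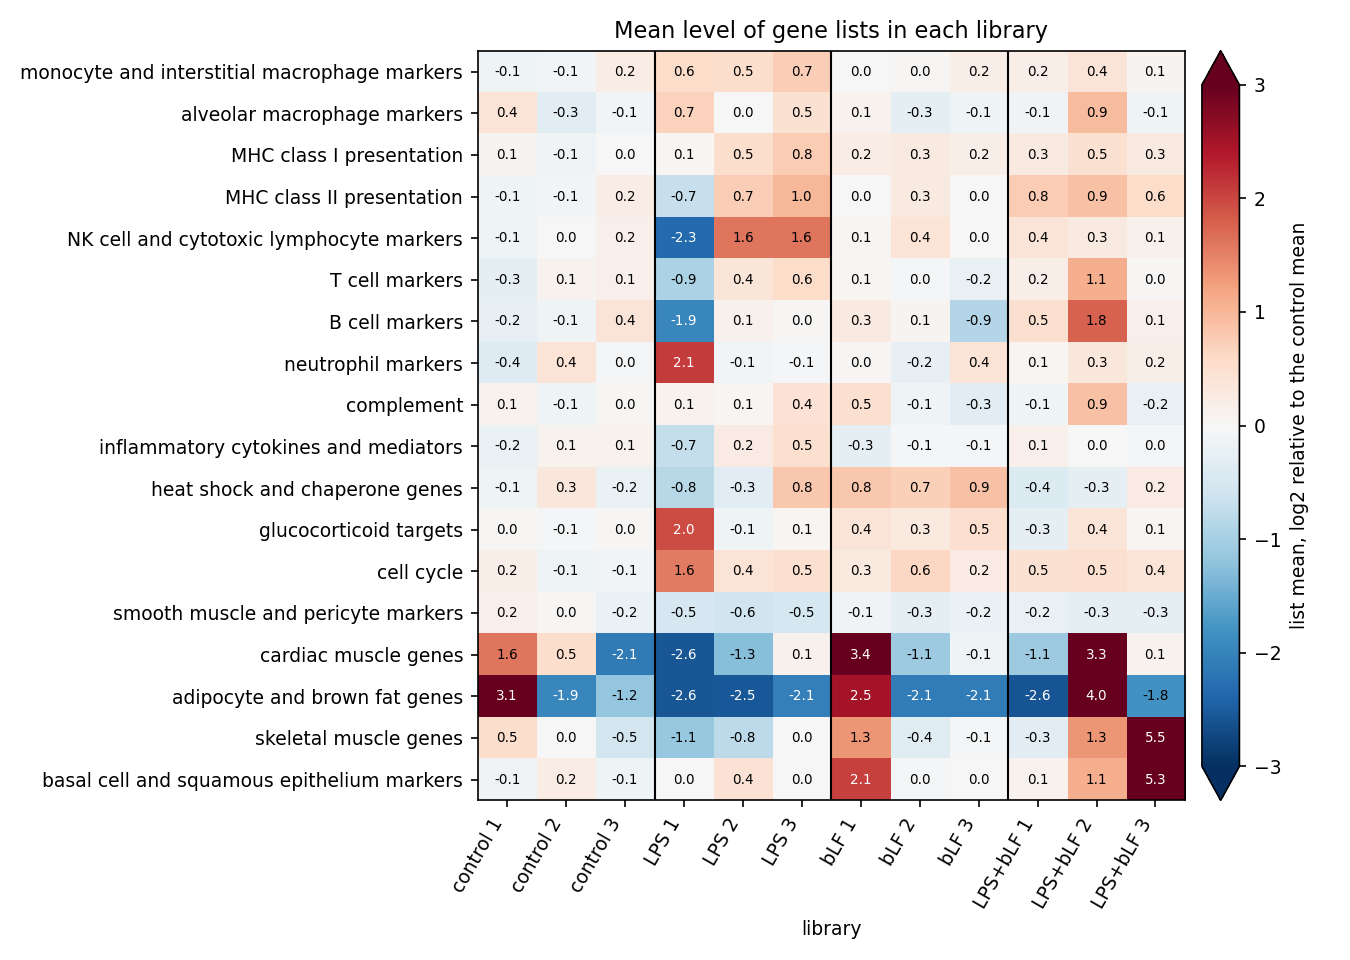
Mean log2 level of the tested members of 18 gene lists (vertical axis) in each of the 12 libraries (horizontal axis), relative to the mean of the 3 control libraries, with the colour scale from −3 to 3 and each value printed. NK cell and cytotoxic lymphocyte markers were at −2.34 in LPS replicate 1 and at 1.6 in both other LPS libraries, and heat shock and chaperone genes were at 0.82, 0.72 and 0.88 in the bLF libraries. LPS replicate 3, without bLF, was at 0.8 for heat shock and chaperone genes.

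LPS versus control asked how gene expression in the lung differed after LPS alone. Macrophage genes were higher in the LPS lungs. Ms4a7, a membrane protein of tissue macrophages (ID 109225, chromosome 19, 11321039 to 11336146, GRCm38), was at 6.51 ± 1.15 FPKM (SD, n = 3) against 1.41 ± 0.323 in control (log2 fold change 2.25 ± 0.30, SE, n = 3). Ctss, the lysosomal protease cathepsin S that trims the invariant chain of MHC class II (ID 13040, chromosome 3, 95526786 to 95556405), was at 228 ± 49.7 against 81.6 ± 28.3 FPKM (SD, n = 3). Of the 29 tested monocyte and interstitial macrophage markers, 24 were higher and 5 lower, with a median log2 fold change of 0.83. The list rose (camera adjusted p = 1.28e-13), was higher than every control library in all 3 LPS libraries, and kept its call at adjusted p = 0.0244 with an estimated correlation, as 1 of 55 lists. Adjusted over the list alone 12 members rose, among them Ms4a7, the adhesion receptor Adgre1 (1.68) and C1qb of the classical complement pathway (1.26), and 0 of all genes passed adjustment over all genes. Alveolar macrophage markers rose too (23 tested, median 0.50, adjusted p = 7.98e-06), with adjusted p = 0.051 with an estimated correlation (0.0277 without LPS replicate 1) and 8 members higher when adjusted over the list alone, including the collagen-degrading cathepsin Ctsk (2.05) and the integrin Itgax (1.06). Their median was 0.15 without LPS replicate 3. List means of alveolar macrophage markers were 0.69, 0 and 0.46 in LPS replicates 1, 2 and 3, and 0.42, −0.33 and −0.09 in control. The highest was 0.95 in LPS+bLF replicate 2, and the fixed list shares Fabp4 and Cidec with the brown fat list.

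Genes of antigen presentation and complement moved the same way. MHC class I presentation genes rose (16 of 18 higher, median 0.51, adjusted p = 1.13e-07), among them the class Ib gene H2-T23 (0.96) and H2-Q4 (1.16), with adjusted p = 0.192 with an estimated correlation (0.0102 without LPS replicate 1) and 6 members called when adjusted over the list alone. Complement genes rose with a median of 0.58 and a mean of 0.14 over 20 genes (adjusted p = 1.48e-07, and adjusted p = 0.131 with an estimated correlation), with 10 called when adjusted over the list alone, including the anaphylatoxin receptor C3ar1 (1.68). Complement list means were 0.1, 0.07 and 0.43 in LPS replicates 1, 2 and 3, and at most 0.1 in control. They were highest in LPS+bLF replicate 2 (0.87) and bLF replicate 1 (0.48). The fixed list shares Cfd with the brown fat list. MHC class II presentation genes had a median of 0.51 (14 tested, adjusted p = 0.000961, and adjusted p = 0.519 with an estimated correlation, with 2 members called when adjusted over the list alone). This call ended without LPS replicate 2 (0.35) and without LPS replicate 3 (0.24), and the median was 0.96 without LPS replicate 1, where the list held at adjusted p = 0.0102 with an estimated correlation.

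Contractile genes were lower after LPS. Myh11, the myosin heavy chain of smooth muscle (ID 17880, chromosome 16, 14194527 to 14292188), was at 12.7 ± 2.33 FPKM against 30.2 ± 8.08 in control (SD, n = 3; log2 fold change −1.22 ± 0.21, SE). Cnn1, the actin-binding calponin, had −1.17 ± 0.28 (SE). Smooth muscle and pericyte markers fell as a list (19 of 22 lower, median −0.47, adjusted p = 7.07e-06, lower than every control library in all 3 LPS libraries), with adjusted p = 0.051 with an estimated correlation (0.0102 without LPS replicate 1) and 3 members called when adjusted over the list alone. Genes of cytochrome P450 and xenobiotic metabolism fell as well (29 of 32 lower, median −0.58, adjusted p = 3.09e-07, and adjusted p = 0.249 with an estimated correlation). Asgr1, a subunit of the asialoglycoprotein receptor (ID 11889, chromosome 11, 70048909 to 70057895), was at 1.84 ± 0.232 FPKM in LPS against 6.64 FPKM in control.

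Other called lists differed in size or call when single libraries were left out. Cell cycle genes rose (32 of 33 higher, median 0.92, adjusted p = 6.53e-14, and adjusted p = 0.196 with an estimated correlation, with 9 called when adjusted over the list alone), and extracellular matrix genes rose (30 of 35 higher, median 0.52, adjusted p = 9.35e-09, and adjusted p = 0.249 with an estimated correlation, with 9 called when adjusted over the list alone). These medians were 0.36 and 0.20 without LPS replicate 1, both still called. Neutrophil markers (median 0.88, adjusted p = 0.00777, and adjusted p = 0.664 with an estimated correlation) had −0.14 without LPS replicate 1, and the call also ended without control replicate 1 (0.86), with 1.37 without control replicate 2. Glucocorticoid targets (median 0.79, adjusted p = 0.000185, and adjusted p = 0.601 with an estimated correlation) had 0.08 without LPS replicate 1, 1.25 without LPS replicate 2 and 1.2 without LPS replicate 3. Acute-phase and antimicrobial proteins (median 0.26, adjusted p = 0.00777, and adjusted p = 0.52 with an estimated correlation) lost the call without LPS replicate 1 (−0.12) or control replicate 1 (0.13), and had 1.37 without control replicate 2, 0.50 without LPS replicate 2 and 0.40 without LPS replicate 3. Brown fat genes (median −3.62, adjusted p = 4.44e-05, and adjusted p = 0.766 with an estimated correlation) had −0.55 without control replicate 1, which ended the call.

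Cytotoxic lymphocyte genes split the LPS group. Nkg7, a granule protein of NK and CD8 T cells, was at 62.62 and 59.03 FPKM in LPS replicates 2 and 3, at 3.74 in LPS replicate 1, and at 13.12 to 18.28 in control. Gzma, the granule protease granzyme A, was at 157.92, 129.48 and 4.8 FPKM in LPS replicates 2, 3 and 1. All 16 NK cell and cytotoxic lymphocyte markers had a higher fitted mean in LPS (median 1.02, adjusted p = 0.0124), with 0 called when adjusted over the list alone and adjusted p = 0.83 with an estimated correlation. The median was 1.55 without LPS replicate 1 (adjusted p = 1.1e-77, and adjusted p = 0.000584 with an estimated correlation), with 15 members called when adjusted over the list alone. The call ended without control replicate 1 (0.97), LPS replicate 2 (0.65) or LPS replicate 3 (0.64). Nkg7 and Gzma were chosen after their values were seen.

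**Figure D2:**
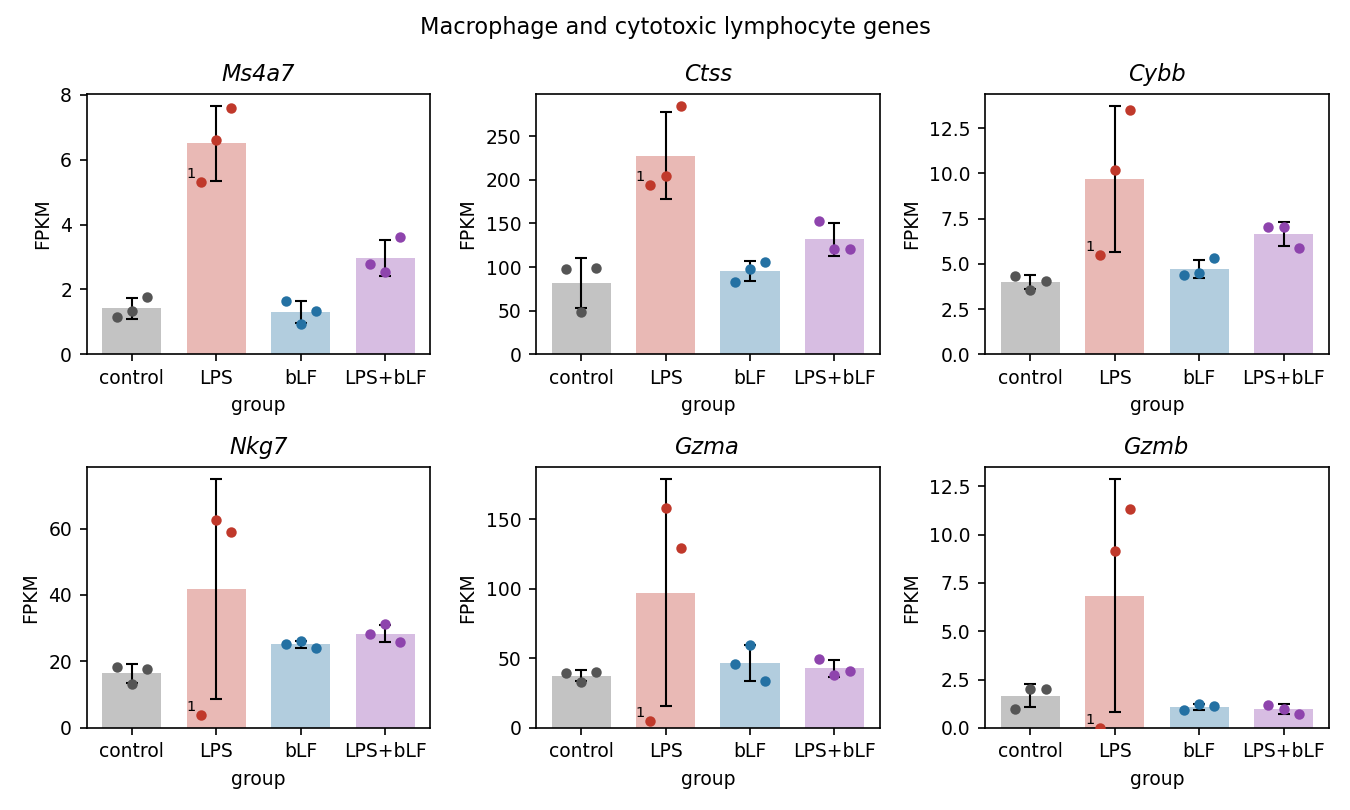
FPKM (vertical axis) of 6 genes of macrophages and cytotoxic lymphocytes in the 4 groups (horizontal axis), with bars for the mean of 3 libraries, error bars for the SD, points for libraries and the digit 1 beside LPS replicate 1. Ms4a7 averaged 6.51 FPKM in LPS and 1.41 in control, and Nkg7 was at 3.74 in LPS replicate 1 and at 62.62 and 59.03 in the other LPS libraries.

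Genes of LPS recognition and NF-kB signalling rose (32 tested, median 0.20, adjusted p = 0.00072, and adjusted p = 0.051 with an estimated correlation, 0.0188 without LPS replicate 1), whereas cytokines as a list did not pass the test. Inflammatory cytokines and mediators had a median of 0.22 (22 tested, adjusted p = 0.148), with 0.40 (adjusted p = 1.43e-06, and adjusted p = 0.0277 with an estimated correlation) without LPS replicate 1 and −0.08 without LPS replicate 3. Interferon-stimulated genes had a median of 0.02 (39 tested, adjusted p = 0.871), were called higher without LPS replicate 1 (0.41, adjusted p = 1.04e-12, and adjusted p = 0.259 with an estimated correlation) and lower without LPS replicate 3 (−0.61, adjusted p = 0.00178, not run with an estimated correlation). Chemokines were called at a median of 0.44 (27 tested, adjusted p = 0.0248, and adjusted p = 0.192 with an estimated correlation, 0.0358 without LPS replicate 1), but not without control replicate 1 (0.36), LPS replicate 2 (0.38) or LPS replicate 3 (0.48), and with 0.29 without control replicate 3. Log2 fold changes were 0.64 ± 0.73 for Tnf, 0.51 ± 0.42 for Il1b, −0.36 ± 0.89 for Cxcl1 and 1.19 ± 0.95 for Ccl2 (SE, n = 3). Saa3 had 4.59 ± 1.78 and Ltf, the gene of the mouse's own lactoferrin, had 3.67 ± 1.61 (SE, n = 3), and without LPS replicate 1 these values were −0.75 and 0.92. Il6 and Cxcl2 were below the minimum for testing. They were at 0.593 ± 0.756 and 1.7 ± 2.13 FPKM in LPS and 0.133 ± 0.0603 and 0.273 ± 0.118 in control (SD, n = 3). Il6 reached 0.5 FPKM in 1 of the 12 libraries and Cxcl2 in 2, with highest values of 1.46 and 4.16 FPKM.

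In LPS versus control edgeR called 0 of 13735 genes, with 980 at an unadjusted p under 0.05 (758 higher and 222 lower) and a smallest adjusted p of 0.084. limma called 2 genes, Ms4a7 and the survival gene Bcl2a1b, and DESeq2 called 139 (130 higher and 9 lower). Without LPS replicate 1 edgeR called 25 genes, all higher, among them Nkg7 (1.85, adjusted p = 0.00118), Gzma (1.89, adjusted p = 0.0146), Cybb of the phagocyte NADPH oxidase (1.52, adjusted p = 0.0146), Ms4a7 (2.28, adjusted p = 0.0238), Ctss (1.59) and Itgax (1.30); Nkg7, Gzma and Cybb were chosen after their values were seen. Of 55 lists 25 were called (19 higher and 6 lower), 1 with an estimated correlation, and fry called 4. Without LPS replicate 1 the list counts were 26 and, with an estimated correlation, 10. No other library was left out with an estimated correlation, so how these calls depend on the other libraries was not tested.

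LPS+bLF versus LPS asked how the lung differed when bLF was given with LPS. Macrophage genes were lower with bLF. Gpnmb, a transmembrane glycoprotein of lipid-loaded macrophages, had a log2 fold change of −2.57 ± 0.55, the Fc receptor Fcgr4 had −1.36 ± 0.32, and Ctsk had −1.49 ± 0.34 (SE, n = 3). Il18rap, a subunit of the interleukin 18 receptor, was at 1.63 FPKM against 4.11 in LPS (−1.38 ± 0.26, SE, n = 3), and H2-T23 was at 163 against 265 FPKM. Asgr1 was at 5.93 ± 1.23 FPKM (SD, n = 3) in LPS+bLF, close to the control mean of 6.64, with a log2 fold change of 1.66 ± 0.34 (SE). Monocyte and interstitial macrophage markers fell (25 of 29 lower, median −0.37, adjusted p = 2.24e-07, and adjusted p = 0.234 with an estimated correlation), with 5 called when adjusted over the list alone: Ms4a7 (−1.13), Gpnmb, Fcgr4, the integrin Itgam (−0.81) and the lipid receptor Trem2 (−1.72), the last pair chosen after their values were seen. Alveolar macrophage markers fell (median −0.50, mean −0.03, adjusted p = 0.000889, and adjusted p = 0.284 with an estimated correlation, with 3 called when adjusted over the list alone), with a median of −0.24 without LPS replicate 1 and −0.17 without LPS replicate 3.

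All 16 NK cell and cytotoxic lymphocyte markers had a lower fitted mean in LPS+bLF than in LPS, with a median of −0.75 that did not pass the test (adjusted p = 0.139). Averaged over libraries on the log2 scale, the list was at 0.26 in LPS+bLF and 0.29 in LPS. LPS replicate 1 (−2.34) lay below all LPS+bLF libraries (0.12 to 0.39). The median was −1.27 without LPS replicate 1 (adjusted p = 2.52e-35, and adjusted p = 0.00904 with an estimated correlation), with 14 members called when adjusted over the list alone, and it was −0.36 without LPS replicate 2 and −0.42 without LPS replicate 3. B cell markers rose (19 of 19 higher, median 1.18, adjusted p = 6.12e-13, and adjusted p = 0.284 with an estimated correlation, with 0 called when adjusted over the list alone), with 0.42 without LPS+bLF replicate 2. Plasma cell and immunoglobulin genes rose (median 0.75, adjusted p = 8.2e-05, and adjusted p = 0.284 with an estimated correlation), with 0.42 and no call without LPS replicate 1 and 0.37 without LPS+bLF replicate 2. In LPS replicate 1 the B cell list mean was −1.95, and in LPS+bLF replicate 2 it was 1.77.

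Lists that were high in LPS replicate 1 were lower in LPS+bLF. Extracellular matrix genes fell (median −0.56, adjusted p = 4.25e-11, and adjusted p = 0.284 with an estimated correlation), with −0.18 without LPS replicate 1. Cell cycle genes fell (25 of 33 lower, median −0.56, adjusted p = 0.000138, and adjusted p = 0.429 with an estimated correlation), with 0.10 and no call without LPS replicate 1. Glucocorticoid targets (−0.79), neutrophil markers (−0.98) and acute-phase and antimicrobial proteins (−0.44) fell, with adjusted p = 0.367, 0.45 and 0.367 with an estimated correlation. These 3 calls ended without LPS replicate 1, at 0.04, 0.25 and 0.09, and the acute-phase list had −1.10 without LPS+bLF replicate 2.

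Muscle, fat and squamous genes were higher in LPS+bLF and followed single libraries. Skeletal muscle genes rose by a median of 5 (11 of 15 called when adjusted over the list alone, and adjusted p = 0.284 with an estimated correlation), with 0.68 without LPS+bLF replicate 3. Basal cell and squamous epithelium markers had 2.61 (adjusted p = 0.367 with an estimated correlation), with 0.42 and no call without LPS+bLF replicate 3 and 4.28 without LPS replicate 1. Cardiac muscle genes had 2.91 (adjusted p = 0.408 with an estimated correlation), with 0.62 without LPS+bLF replicate 2 and 4.48 without LPS replicate 3. Brown fat genes (4.47) and nuclear genes of oxidative phosphorylation, the pathway of mitochondrial ATP synthesis (0.68), had −0.07 and 0.06 without LPS+bLF replicate 2, which ended both calls (adjusted p = 0.474 and 0.408 with an estimated correlation).

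For LPS+bLF versus LPS edgeR called 0 of 13735 genes, with 950 at an unadjusted p under 0.05 (449 higher and 501 lower) and a smallest adjusted p of 0.689. limma called 0, and DESeq2 called 7, with Asgr1 (1.66) and Ino80b (0.42) higher and Gpnmb (−2.61), Il18rap (−1.40), H2-Bl (−1.27), Gm11127 (−1.01) and H2-T23 (−0.72) lower, of which Ino80b and Gm11127 were chosen after their values were seen. Without LPS replicate 1 edgeR called 2 genes, the granzymes Gzmb (−3.31) and Gzma (−1.65), both with adjusted p = 0.0494 and both chosen after their values were seen. Of 55 lists 33 were called (15 higher and 18 lower), 0 with an estimated correlation and 0 by fry.

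Among the fixed inflammatory and epithelial genes, values in LPS+bLF versus LPS were near 0 for Tnf (0.05), Ager (−0.12) and Sftpc (−0.25). Saa3 (−3.58), Ccl2 (−2.13), Ltf (−2.59) and the haem-degrading enzyme Hmox1 (−1.93) had larger values, which without LPS replicate 1 were 1.77, −0.27, 0.16 and −0.17. Lcn2, an iron-siderophore-binding protein of neutrophils and epithelium, had −1.34 and, without that library, −0.92. Their adjusted p were all 0.689 or above.

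A gene called in LPS versus control and the opposite way in LPS+bLF versus LPS would have moved toward or past its control level. With all 12 libraries edgeR found 0 such genes. In 20 simulated data sets of 12 libraries with no changed gene and the same shared libraries, the mean was 0.05 such genes and the highest 1. There were 2 without LPS replicate 1, Gzma and Gzmb, for which no simulated count was made. Across the 13735 genes, which are not independent replicates, the log2 fold changes of both comparisons had r = −0.73. Both share the LPS libraries, and the simulated data sets gave a mean of −0.5, from −0.53 to −0.46. The covariance was −0.391, against a simulated mean of −0.13. For LPS versus control with bLF versus control, r also left its simulated range (0.33, simulated 0.47 to 0.54). With LPS+bLF versus control it did too (0.23, simulated 0.46 to 0.55). Without LPS replicate 1 the −0.73 was −0.72, with no simulation made. Simulated genes had 1 dispersion for all libraries, so no library stood apart as LPS replicate 1 did. The difference from the simulated values therefore cannot tell an effect of bLF from the spread between libraries.

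bLF versus control asked how bLF alone altered the lung. Chaperone genes were higher in the bLF lungs. Dnaja1, an HSP40 partner of HSP70, was at 165 ± 4.93 FPKM against 85.5 ± 13.7 in control (SD, n = 3), and Chordc1, a partner of HSP90, was at 65.5 ± 5.15 against 35.3 ± 9.78. Bag3, a co-chaperone of HSP70 (ID 29810, chromosome 7, 128523583 to 128546981), was at 55.9 ± 4.42 against 34.1 ± 4.86 FPKM (log2 fold change 0.74 ± 0.20, SE, n = 3). All 15 heat shock and chaperone genes were higher, and the list rose (median 0.74, adjusted p = 3.96e-20, higher than every control library in all 3 bLF libraries), with adjusted p = 0.255 with an estimated correlation. LPS replicate 3, which had no bLF, had a list mean of 0.8, within the range of the bLF libraries (0.82, 0.72 and 0.88). LPS replicates 1 and 2 had −0.83 and −0.34. Adjusted over the list alone 4 members rose, namely Bag3, Chordc1, Dnaja1 and the cytosolic HSP90 gene Hsp90ab1 (0.84), the last chosen after its values were seen. Nr4a1, an orphan nuclear receptor and immediate-early gene (ID 15370, chromosome 15, 101253902 to 101274795), was at 12.1 ± 1.37 FPKM against 25.4 ± 4.88 in control (SD, n = 3; log2 fold change −1.04 ± 0.19, SE).

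**Figure D3:**
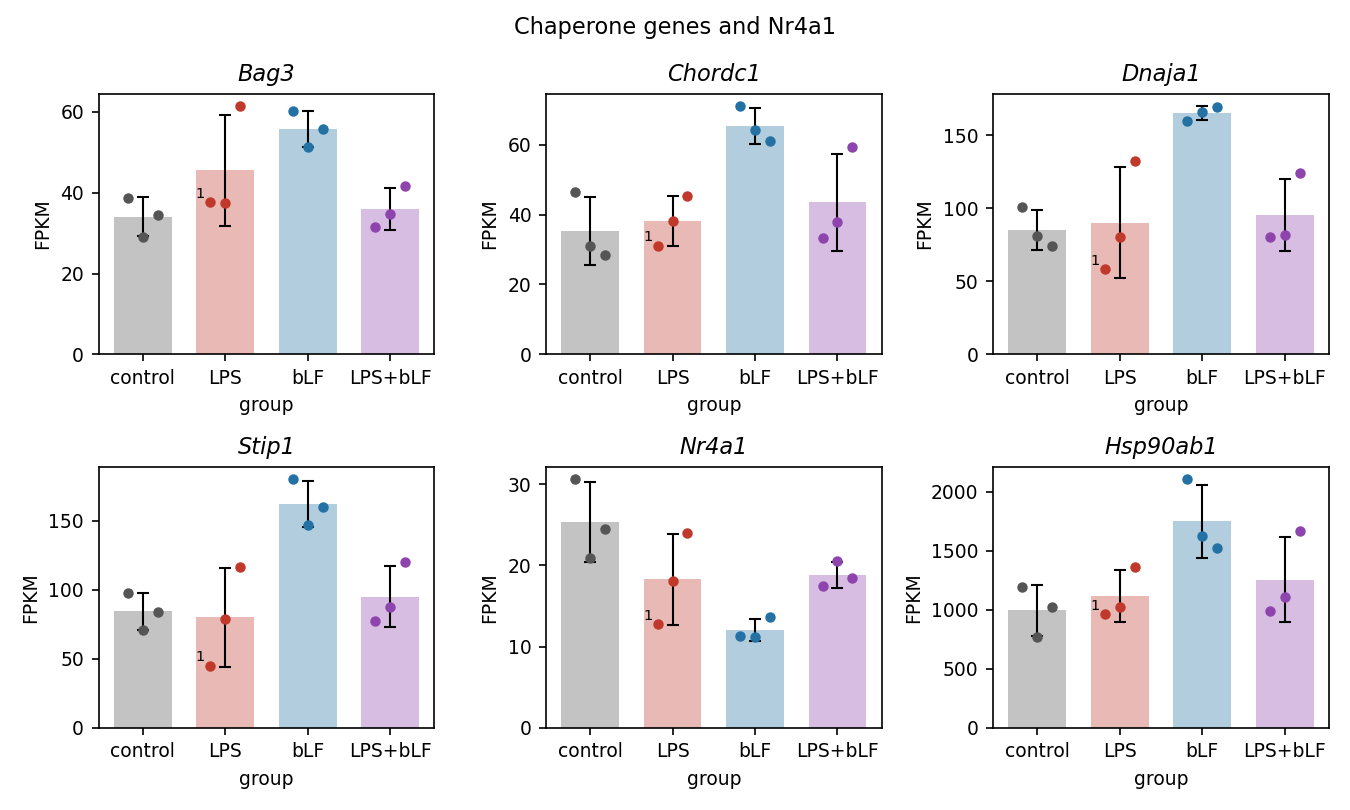
FPKM (vertical axis) of 5 chaperone genes and Nr4a1 in the 4 groups (horizontal axis), with bars for the mean of 3 libraries, error bars for the SD, points for libraries and the digit 1 beside LPS replicate 1. Dnaja1 averaged 165 FPKM in bLF and 85.5 in control, and Nr4a1 averaged 12.1 and 25.4.

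Cell cycle genes rose in the bLF lungs (32 of 33 higher, median 0.37, adjusted p = 6.33e-10, and adjusted p = 0.635 with an estimated correlation), as did MHC class I presentation genes (13 of 18 higher, median 0.16, adjusted p = 0.000368, and adjusted p = 0.635 with an estimated correlation). Cholesterol biosynthesis genes fell (17 of 20 lower, median −0.16, adjusted p = 0.00149, and adjusted p = 0.635 with an estimated correlation), and in these 3 lists 0 members were called when adjusted over the list alone. Klf15, a metabolic transcription factor induced by glucocorticoids, was at 35.7 against 20.9 FPKM. Immediate-early genes fell (median −0.19, adjusted p = 0.000846, and adjusted p = 0.659 with an estimated correlation), with Nr4a1 as the 1 member called when adjusted over the list alone; their median was −0.07 without control replicate 1, which ended the call, and −0.11 without control replicate 2.

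Other called lists in bLF versus control lost their call when single libraries were left out, some at medians as large as with all 12. Glucocorticoid targets (median 0.34, adjusted p = 0.903 with an estimated correlation) lost the call without control replicate 1 (0.61) or bLF replicate 3 (0.37), and platelet genes (0.46, adjusted p = 0.635 with an estimated correlation) lost it without bLF replicate 3 (0.08). Erythroid genes (0.17, adjusted p = 0.903 with an estimated correlation) lost it without control replicate 1 (0.14), control replicate 2 (0.05), bLF replicate 1 (0.11) or bLF replicate 3 (0.05), with 0.38 without control replicate 3 and 0.41 without bLF replicate 2. Smooth muscle and pericyte markers (−0.18, adjusted p = 0.635 with an estimated correlation) lost it without control replicate 1 (−0.10), bLF replicate 2 (−0.14) or bLF replicate 3 (−0.27), with −0.34 without control replicate 3. Cardiac muscle genes (1.52, adjusted p = 0.979 with an estimated correlation) lost it without control replicate 3 (0.97) and turned to −1.21 without bLF replicate 1.

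With bLF alone edgeR called 0 of 13735 genes, with 189 at an unadjusted p under 0.05 (98 higher and 91 lower) and a smallest adjusted p of 1. These 189 are less than a share of 0.05 of the tested genes, which unchanged genes alone would give. limma called 0, and DESeq2 called 1, Nr4a1 (−1.04, adjusted p = 0.00492). Of 55 lists 10 were called (7 higher and 3 lower), 0 with an estimated correlation and 0 by fry. All 10 splits of the bLF and control libraries into groups of the same sizes called at least as many lists. The highest other split called 22, so the list count does not set the real groups apart. The count of lists was 19 without control replicate 2 and 18 without bLF replicate 2.

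LPS+bLF versus control asked what remained different from untreated lung when both were given. Antigen presentation genes were higher. Siglece, an inhibitory sialic acid receptor of myeloid cells (ID 83382, chromosome 7, 43648882 to 43672044), was at 13.5 against 6.73 FPKM in control (log2 fold change 1.02 ± 0.18, SE, n = 3), and the interleukin 10 receptor gene Il10ra was at 14.1 against 7.30. All 14 MHC class II presentation genes were higher, and the list rose (median 0.77, adjusted p = 7.86e-08, higher than every control library in all 3 LPS+bLF libraries), with adjusted p = 0.405 with an estimated correlation and 0 members called when adjusted over the list alone. MHC class I presentation genes rose (15 of 18 higher, median 0.36, adjusted p = 1.97e-05), and cell cycle genes rose (29 of 33 higher, median 0.41, adjusted p = 2.77e-06), both with adjusted p = 0.405 with an estimated correlation and 0 members called when adjusted over the list alone. Myh11 had −0.85 ± 0.21 (SE, n = 3).

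Dendritic cell markers rose in LPS+bLF over control (median 1.05, adjusted p = 2.88e-05, and adjusted p = 0.405 with an estimated correlation, with the transcription factor Batf3 called when adjusted over the list alone), as did B cell markers (19 of 19 higher, median 0.89, adjusted p = 1.91e-07, and adjusted p = 0.405 with an estimated correlation). Without LPS+bLF replicate 2 these medians were 0.18 and 0.21, both still called. T cell markers (0.66, adjusted p = 3.12e-05, and adjusted p = 0.458 with an estimated correlation) lost the call without control replicate 1 (0.57) or LPS+bLF replicate 2 (0.25). Monocyte and interstitial macrophage markers (0.22, adjusted p = 0.00206, and adjusted p = 0.405 with an estimated correlation) had 4 members called when adjusted over the list alone, including Ms4a7 (1.12) and C1qb (0.85). They lost the list call without control replicate 1 (0.43), and had 0.10 without LPS+bLF replicate 2 and 0.37 without LPS+bLF replicate 3.

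Smooth muscle and pericyte markers in LPS+bLF fell (median −0.42, adjusted p = 0.00492, and adjusted p = 0.405 with an estimated correlation), with Myh11 called when adjusted over the list alone and no list call without control replicate 1 (−0.16). Alveolar type 1 cell markers fell (−0.29, adjusted p = 0.00492, and adjusted p = 0.636 with an estimated correlation), with no call without control replicate 3 (−0.19) or LPS+bLF replicate 2 (−0.12) and −0.50 without LPS+bLF replicate 1. Skeletal muscle genes (4.52) and basal cell and squamous epithelium markers (4.07) rose, both with adjusted p = 0.405 with an estimated correlation. Both lost the call without LPS+bLF replicate 3 (0.69 and 0.37), and the squamous list also without control replicate 1 (3.72).

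With both treatments edgeR called 0 of 13735 genes against control, with 660 at an unadjusted p under 0.05 (361 higher and 299 lower) and a smallest adjusted p of 0.832. These 660 too are less than the share of 0.05 that unchanged genes alone would give. limma called 0 and DESeq2 called 13 (11 higher and 2 lower), among them Siglece and Il10ra. Of 55 lists 24 were called (17 higher and 7 lower), 0 with an estimated correlation and 0 by fry.

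The interaction asked whether bLF acted differently with LPS than without it. Bag3 had −1.08 ± 0.29 and H2-T23 had −0.97 ± 0.25, whereas Nr4a1 had 1.10 ± 0.27 and Asgr1 had 1.85 ± 0.47 (log2 units, SE, n = 3). Heat shock and chaperone genes had a negative interaction (13 of 15 lower, median −0.76, adjusted p = 4.24e-09, and adjusted p = 0.285 with an estimated correlation), which was −0.91 without LPS replicate 1. The list mean was −0.83, −0.34 and 0.8 in LPS replicates 1, 2 and 3, and replicate 3 was not left out here. Monocyte and interstitial macrophage markers (−0.58, adjusted p = 1.43e-07, and adjusted p = 0.215 with an estimated correlation) and MHC class I presentation genes (−0.39, adjusted p = 0.000178, and adjusted p = 0.298 with an estimated correlation) were lower in the same sense, at −0.40 and −0.36 without LPS replicate 1. NK cell and cytotoxic lymphocyte markers had −1.12 (adjusted p = 0.0372, and adjusted p = 0.674 with an estimated correlation), and −1.62 without LPS replicate 1 (adjusted p = 1.32e-43, and adjusted p = 0.00467 with an estimated correlation). B cell markers had 1.36 (adjusted p = 6.29e-12, and adjusted p = 0.298 with an estimated correlation). The B cell list mean was −1.95 in LPS replicate 1, 1.77 in LPS+bLF replicate 2 and −0.89 in bLF replicate 3. In the other libraries it was −0.25 to 0.47.

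For the interaction edgeR called 0 of 13735 genes, with 384 at an unadjusted p under 0.05 (173 higher and 211 lower) and a smallest adjusted p of 1. The 384 are likewise less than the share of 0.05 that unchanged genes alone would give. limma called 0, and DESeq2 called 1, Gm10499 (−1.46, adjusted p = 0.0175), chosen after its values were seen. Of 55 lists 27 were called (12 higher and 15 lower), 0 with an estimated correlation and 0 by fry. Of the 12 libraries only LPS replicate 1 was left out for the lists of this comparison.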

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

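The tests of a wrong label for LPS replicate 1, of treatment as the source of brown fat genes, and of all 3 explanations for the cytotoxic genes were chosen only after the result was seen.

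A test of the difference itself drew attention to the interaction of LPS and bLF. The effect of bLF with LPS differed from its effect without LPS in 27 of 55 gene lists, 12 higher and 15 lower, and 0 of these calls held with an estimated correlation. In 100 splits of the libraries into groups of the same sizes, 30 called as many lists, and the highest other split called 35, so chance is not excluded. For the count of genes of the interaction, all 100 splits gave at least the real 0, as any split must, so this count tests nothing. The highest other split gave 49, and its cause was not tested.

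LPS replicate 1 stood apart from the other 11 libraries, with the genes of cytotoxic lymphocytes low and those of neutrophils and glucocorticoid targets high. The tables argue against fewer counts, since thinning the other libraries to its total left at most 2005 genes at 0 against its 3068 in rounded counts, and against a trend on transcript length and GC content, which took 0.7% of the variance of its deviation and left the cytotoxic list at −2.54 ± 0.26 (SE over 16 members) from −2.74 ± 0.26. An untreated lung under a wrong label was tested in 3 ways, each chosen after the values were seen: 16 of 20 macrophage genes picked as higher than the same controls lay above every control library, which that choice makes void, and a count of all 52 macrophage genes was undecided (53.8% above every control, against 36.5% in the highest bLF library, where 35.7% and 16.6% of all tested genes were). The last argues against it as the cause of this library standing apart, since the correlation with the control libraries was at most 0.888, below the 0.921 to 0.983 of the 15 pairs of control and bLF libraries, but it largely restates the pattern and leaves open whether the label is right. A difference of this animal in its response, its handling or the piece of lung taken stays open and was not tested. The same holds for the RNA of this library and its preparation, which the total count does not cover.

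Brown fat and heart muscle genes were high in control replicate 1, bLF replicate 1 and LPS+bLF replicate 2, with brown fat list means of at least 2.5 and at most −1.17 in the other libraries, and Ucp1 at 88.08, 57.37 and 157.72 FPKM. A treatment shared by a group does not account for them, since at most 1 library of any group was among the 3 and 1 of these was a control, which restates the pattern and is no separate test. Pieces of fat and heart tissue beside the lung may be the source. The excess over the other libraries correlated across genes between these 3 libraries at 0.98 to 0.99 for brown fat and at 0.71 to 0.89 for heart muscle, and genes are not independent replicates; in the other libraries 19 of 26 brown fat and 25 of 28 heart muscle genes had a mean of at least 1 CPM. Neighbouring tissue and a change of the lung itself cannot be told apart, because no sample of either tissue alone was sequenced.

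Cytotoxic lymphocyte genes were higher in LPS replicates 2 and 3 than in the control libraries. A larger share of leukocytes of every kind is argued against for these 2 libraries, since the cytotoxic list exceeded the T cell list by 1.2. Mean log2 fold changes were 1.64, 0.44 and 0.02 for cytotoxic, T and B cell markers without LPS replicate 1. The SE of the difference, 0.17, was taken over 16 and 22 list members, which are not independent. It does not measure the spread between animals. In LPS replicates 2 and 3 the list means were 1.6 and 1.6 for cytotoxic and 0.36 and 0.56 for T cell markers. Scaling is argued against, since under 3 other scalings the cytotoxic mean was between 1.64 and 1.69. A response to LPS shared by the group could be the source, but 2 of 3 LPS libraries lay above every control library and the other far below, and 2 LPS+bLF libraries (0.39 and 0.28) and bLF replicate 2 (0.40), which had no LPS, were above every control library (at most 0.16) too. With 3 libraries a shared response and a difference between animals cannot be told apart.

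With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes of LPS versus control, 10 of 10 splits gave at least the real 0, with 0 as the highest other count. Corresponding values were 10 of 10 with a highest other count of 2 for LPS+bLF versus LPS, 10 of 10 and 0 for bLF versus control, and 10 of 10 and 0 for LPS+bLF versus control. For lists, as many as the real 25 were called in 3 splits for LPS versus control (highest other 28), as many as 33 in 1 split for LPS+bLF versus LPS (29), as many as 10 in 10 splits for bLF versus control (22), and as many as 24 in 2 splits for LPS+bLF versus control (25). Without LPS replicate 1, the real split of LPS versus control gave 25 genes and was the 1 split of 10 with as many, where the highest other gave 0. With array weights the real split gave 5901 genes and 2 of 10 splits gave as many, with 7173 in the other. For genes called in opposite directions, 100 of 100 splits gave at least the real 0, as any split must, so this count tests nothing; the highest other gave 2.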

How the results depend on the processing

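DESeq2, RLE factors, library size alone and the omission of 2 or 5 libraries were tests chosen only after the results were seen, whereas limma on log2(FPKM + 1) had been written as the test and became an alternative after the data were seen. Of the alternative values for counts of genes and lists, 259 stayed within 1.5 times the reported count and 34 moved. Named lists kept their side of the threshold in 1392 alternative values (10 of them not called and with a median of the other sign). With the test direction kept, they lost the call in 132 (12 with a median of the other sign) and gained it in 13. The camera test turned direction in 27. Some of the 27 also lost the call, such as neutrophil markers in LPS versus control with array weights (adjusted p = 0.374). Named genes, none of which was called as reported, stayed not called in 7051 values, of which 82 had the other sign, were called in the same direction in 206, and in the other direction in 3. Depth limits genes near a count of 0, and with 3 libraries per group the spread between animals limits small changes of the rest. In simulated counts of LPS versus control edgeR recovered 15% of changed genes at a log2 fold change of 1 and 76% at 2. Without 5 libraries the LPS+bLF group held 1 library, which was assumed to vary like the other groups. For the values that moved or turned, the cause was not tested.

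Counts of called genes in LPS versus control were 0 as reported, 3 with a pseudocount of 5, 1 with TPM, 12 with quantile normalization, 5901 with array weights, 2 with limma, 139 with DESeq2, 16 without LPS replicate 1 and LPS+bLF replicate 3, 12 without 5 libraries, and 0 to 25 leaving out 1 library. For LPS+bLF versus LPS they were 0 as reported, 144 with array weights, 7 with DESeq2 and 0 to 2 leaving out 1 library. For bLF versus control they were 1897 with array weights, 1 with DESeq2 and 2 without 5 libraries, and for LPS+bLF versus control 3385, 13 and 2. The interaction had 34 genes with array weights and 1 with DESeq2. Genes called in opposite directions numbered 109 with array weights, 6 with DESeq2 and 0 to 2 leaving out 1 library. Array weights were 17.02 for control replicate 3, 12.79 for LPS replicate 2 and 0.07 for LPS replicate 1.

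Called lists in LPS versus control numbered 25 as reported, 15 with array weights, 1 with an estimated correlation (10 without LPS replicate 1) and 18 to 28 leaving out 1 library. In LPS+bLF versus LPS they were 33, 21, 0 and 22 to 34. In bLF versus control they were 10 as reported, 16 with only the 2 groups, 0 with an estimated correlation and 7 to 19 leaving out 1 library. In LPS+bLF versus control they were 24 as reported, 12 with array weights, 0 with an estimated correlation, 14 without 5 libraries and 18 to 29 leaving out 1 library.

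Test directions turned with array weights for these medians: neutrophil markers −0.09 and glucocorticoid targets −0.08 in LPS versus control, glucocorticoid targets −0.15, neutrophil markers 0.00, acute-phase proteins −0.17 and cell cycle −0.02 in LPS+bLF versus LPS, and erythroid genes −0.09 and smooth muscle markers −0.02 in bLF versus control. Ccl2 (−0.48), S100a9 (−0.61) and Tfrc (0.39) turned in LPS versus control. Without LPS replicate 1 and LPS+bLF replicate 3, neutrophil markers (−0.14) and glucocorticoid targets (0.08) turned in LPS versus control, and neutrophil markers (0.27) and cell cycle (0.07) in LPS+bLF versus LPS. Leaving out 1 library gave these a range of −0.14 to 1.37, 0.08 to 1.25, −1.42 to 0.25 and −0.84 to 0.10, with the turn in each without LPS replicate 1. Interferon-stimulated genes ranged from −0.61 (without LPS replicate 3) to 0.41, and cardiac muscle genes in bLF versus control from −1.21 (without bLF replicate 1) to 2.18. Without 5 libraries, acute-phase proteins (−0.04) and neutrophil markers (−0.33) turned in LPS versus control, neutrophil markers (0.01), cell cycle (0.06), cardiac muscle (−0.60), brown fat (−0.27) and squamous genes (−0.08) in LPS+bLF versus LPS, and cardiac muscle (−0.33) and immediate-early genes (−0.01) in bLF versus control.

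With the replicate number as a replicate block, 0 genes were called in each comparison and 26, 33, 10 and 25 lists in the 4 comparisons of groups. The numbers do not pair the libraries: deviations of libraries with the same number correlated at −0.69 to 0.57, 5 of 18 such pairs were over 0.1, and 2 of 12 libraries correlated best with their own number.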

Other observations

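The relation of glucocorticoid targets with lymphocyte genes was a test chosen only after the result was seen.

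Several fixed lists related to the iron-binding and signalling roles of lactoferrin were not called. Iron handling genes, which transport, store and export iron, had a median log2 fold change of −0.10 in LPS versus control (29 tested, adjusted p = 0.836), −0.09 in bLF versus control (adjusted p = 0.475) and −0.04 in LPS+bLF versus LPS (adjusted p = 0.392). NRF2 and oxidative stress genes had −0.13, −0.10 and 0.10 in the same comparisons (38 tested, adjusted p = 0.871, 0.696 and 0.301). The transferrin receptor gene Tfrc had −0.31 in LPS versus control and 0.26 in LPS+bLF versus LPS. Members of the MAP kinase, Rap1 and PI3K signalling list had 0.04, −0.05 and −0.05 (29 tested, adjusted p = 0.823, 0.95 and 0.455).

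A stress hormone response in the animal of LPS replicate 1 may be a source of its high glucocorticoid targets and low lymphocyte genes, as a hypothesis. Glucocorticoids raise their target genes and lower lymphocyte numbers, so an inverse relation of both measures was looked for in the other animals as well. It would be seen there only if those animals had such a response too. Their glucocorticoid list means were −0.29 to 0.5, against 1.96 in LPS replicate 1. A lack of relation among them therefore cannot argue against the hypothesis. Over 11 libraries without it, Spearman's rho with the B cell, T cell and cytotoxic lists was −0.16, −0.25 and −0.21 (permutation p = 0.638, 0.464 and 0.529, adjusted p = 0.638 for each of the 3 relations), and Pearson's r was 0, 0.01 and −0.32 (permutation p = 0.991, 0.971 and 0.337, adjusted p = 0.991). Over all 12 libraries rho was −0.35, −0.42 and −0.39 (permutation p = 0.26, 0.174 and 0.203, adjusted p = 0.26) and r was −0.65, −0.61 and −0.81 (permutation p = 0.0647, 0.0786 and 0.0143, adjusted p = 0.0786, 0.0786 and 0.0429). Leaving out the 2 libraries farthest from the median of the glucocorticoid list gave r of 0.4, 0.25 and −0.24, so the relation rests on those libraries, and the hypothesis stays open.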
